A study of Mus musculus with 16 samples.

How the data were processed

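RNA of 2 MMTV-PyMT mouse mammary tumour cell lines was measured by sequencing in 16 samples. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum. TGFb was given at 2 ng/ml for 4 days and Wnt3a at 100 ng/ml for 3 days, each beside its own untreated cells. RNA was extracted on miRNeasy columns with DNase treatment, 200 ng went into TruSeq Stranded mRNA libraries, and single reads of 75 bases were read on a NextSeq. The submitters' processing notes name STAR and the mm10 build. The STAR version, counting tool, strand setting and gene annotation are not given in the sources used here.

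The authors deposited 1 table of counts with 19665 rows of Entrez gene IDs and 16 columns. Its values are whole-number counts of reads per gene, although its name speaks of CPM. All 16 columns matched a sample's title. They fell into 8 groups of 2 replicates. Gene symbols and coordinates came from NCBI's GRCm38.p6 gene table, which named 19613 of the IDs, and the remaining 52 were tested without a name. The mitochondrially encoded genes were not analysed here. GC content and transcript length came from GENCODE M21 and covered 13077 of 13172 genes tested (99.3%).

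Genes with a CPM of at least 1 in at least 2 libraries entered the tests. Libraries were scaled with TMM. Since the values were counts, edgeR's quasi-likelihood test replaced limma on log2 values, planned for CPM. A single model with 1 mean per group was fitted to all 16 libraries (8 residual degrees of freedom, prior degrees of freedom 4.05, common biological coefficient of variation 0.26). The contrasts were TGFb against untreated in each line, Wnt3a against untreated in each line, AE against WT over both sets of untreated libraries, and the difference between the lines in each response, taken as AE minus WT. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of F.

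Of 28 gene lists written beforehand, 27 had at least 3 tested members. They were tested against the other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjusted p-values over the 27 lists of a comparison. The design, the lists, the main alternatives and the rule for naming genes were fixed before the data were examined. That rule took Pygo2, the 5 largest and 5 smallest log2 fold changes among passing genes without overlap between libraries and with a group mean of at least 5 CPM, and per list up to 4 passing members or, where none passed, up to 2 with the highest CPM. Of these list members the text names 1 to 3 per list, and few where none passed, a choice for length made after their values were seen. Some genes met by the rule are not reported here.

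A group at 0 counts was set to 3 counts over the group for a lower bound of a fold. With 1 to 3 counts the ratio is given with its 95% counting interval. Replicates were compared first: the chi-square per degree of freedom between the replicates of a group ran from 4.70 to 203, so no pair agreed within sampling noise, and all 16 libraries were kept. The steps were tested on simulated counts with 100 genes changed at each size. For TGFb in WT (13048 genes) 11% of 2-fold and 80% of 4-fold changes were recovered, with 6 false calls among 97. For Wnt3a in WT (13071 genes) the shares were 10% and 78%, with 2 false calls among 90. For the TGFb difference (12953 genes) they were 0% and 32%, with 0 false calls among 32. With this pooled spread a 2-fold difference between the lines is likely missed. The 3-day replicates differed more, so the Wnt3a values need not hold.

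Alternatives fixed in advance were median-ratio and quantile scaling, no filter or a minimum of 5 CPM, no intensity trend, limma on log2(CPM + 0.1), a fold threshold, only the groups compared, the untreated times apart, the replicate number as a block and each library left out in turn. Chosen after seeing the data were DESeq2, limma on log2(CPM + 1), total-count scaling, the libraries of 1 experiment alone, replicate blocks crossed between or set within the lines, the 3-day AE libraries with much Lars2 left out, and a correction for GC content and transcript length, a spline trend with 5 degrees of freedom on each per library, entered as offsets. The correction also removes any true difference between the lines that follows GC content or length. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and numpy 2.4.6.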

Results

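Messenger RNA was sequenced from 2 mouse mammary tumour cell lines of the MMTV-PyMT breast cancer model. Line 631 carried wild-type Pygo2 (WT), and line 828 was homozygous for the A342E knock-in (AE). Pygo2 is a nuclear co-factor of beta-catenin whose PHD finger binds methylated histone H3, and the substitution lies in that finger. Each line was grown untreated or with TGFb for 4 days, and untreated or with Wnt3a for 3 days. The 8 groups held 2 libraries each, biological duplicates per the submitters. The labels do not say how these were grown, so p-values measure the spread between these samples, pooled over both experiments. The 3-day replicates differed more, so Wnt3a p-values are likely too low and TGFb ones too high. The deposited counts summed to 20530538 to 26191846 per library over 19665 genes, of which 13172 passed the count filter and were tested. Levels are given as mean ± SD in CPM, counts relative to the library's total, after TMM scaling, from untreated to treated or from WT to AE, with n = 2 libraries per group unless another number is stated. Every q is a gene's p from edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted over all genes tested. Genes given as the largest changes had no overlap between the libraries of the groups compared or, for response differences, between the changes in WT and in AE. Each genotype had 1 line, so genotype and line cannot be separated in any difference between WT and AE.

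Pygo2 itself (Entrez 68911, a protein-coding gene on chromosome 3 from 89430114 to 89435131, GRCm38.p6) had group means of 49.6 to 64.9 CPM. In untreated libraries it stood at 55.3 ± 6.1 CPM in WT and 52.3 ± 4.2 CPM in AE (n = 4 per line, log2 fold change -0.08 ± 0.11, adjusted p = 0.59). The changes under treatment were 0.11 ± 0.16 with TGFb in WT (adjusted p = 0.69), 0.09 ± 0.16 with TGFb in AE (adjusted p = 0.85), 0.18 ± 0.16 with Wnt3a in WT (adjusted p = 0.49) and 0.05 ± 0.16 with Wnt3a in AE (adjusted p = 0.92). The difference between the lines in either response did not pass (adjusted p = 1.0 for TGFb and 0.73 for Wnt3a). With a correction for GC content and transcript length, chosen after the data were seen, Pygo2 passed as lower in AE. That correction also re-centres each library's mean log2 level, so the call need not come from GC content or length. Since a point mutation need not alter its transcript's level, these counts do not check the genotype labels.

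The first principal component of log2 CPM held 62.0% of the variance and parted the 2 lines, and the second held 16.1%. Replicates of the 4-day experiment lay close together, with an SD of the log2 ratio of replicate 1 over replicate 2 between 0.24 and 0.43 across genes. In the 3-day experiment it was 0.92 and 0.86 in untreated and Wnt3a-treated WT and 0.78 and 0.45 in untreated and Wnt3a-treated AE. In WT this ratio followed transcript GC content, with a Spearman rho across genes of -0.68, -0.71, -0.74 and -0.64 in the untreated and TGFb-treated 4-day and the untreated and Wnt3a-treated 3-day pairs. In AE the values were 0.45, 0.00, 0.63 and 0.23 in the same order. In every group replicate 2 held more of Lars2 and of 1 unnamed Entrez ID than replicate 1. In both 3-day AE groups it held most, with Lars2 at 0.128% and 0.157% of counts (others at most 0.0359%). The ID stood at 0.643% and 1.186% there (others at most 0.204%). The cause was not tested.

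**Figure D1:**
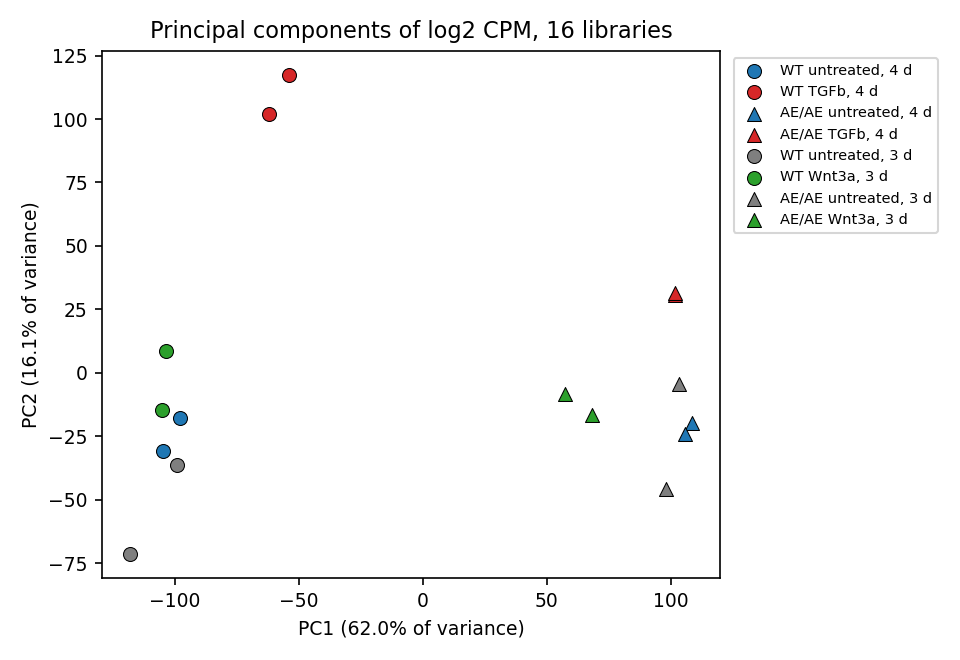
The 16 libraries on the first (62.0% of the variance) and the second (16.1%) principal component of log2 CPM, 1 point per library. The WT and AE libraries sit on opposite sides of the first component.

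**Figure D2:**
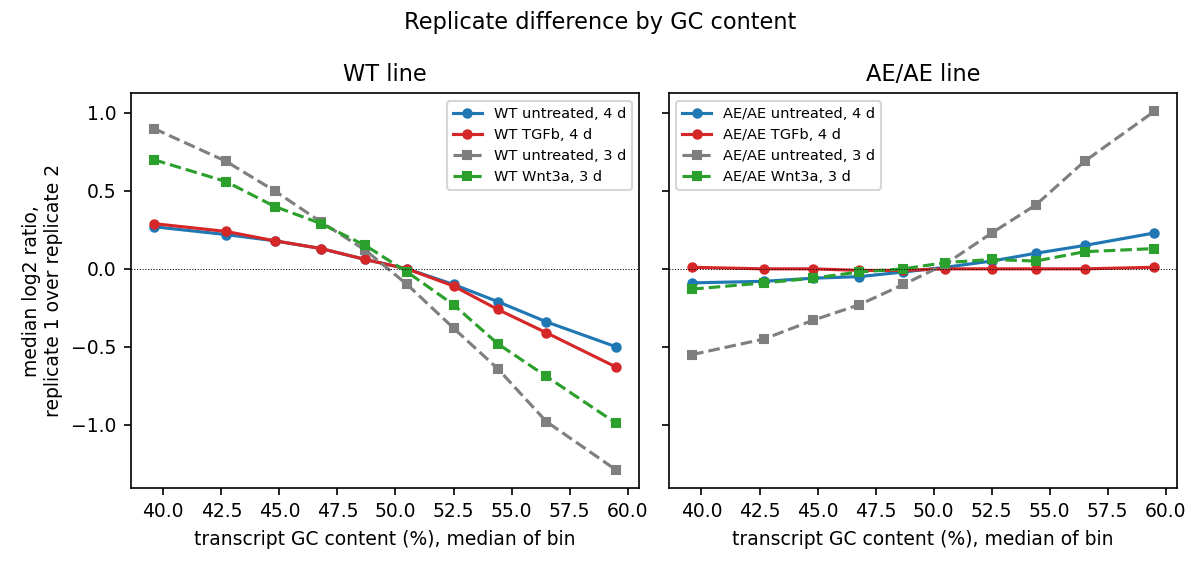
Median log2 ratio of replicate 1 over replicate 2 (y axis) in 10 bins of transcript GC content (x axis, percent), with 1 line per group. The lines fall with rising GC content in the 4 WT groups, and rise in untreated AE at both times.

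TGFb changed 3634 genes in the WT line, 1930 higher and 1704 lower. All 30 S phase genes and all 30 G2 and mitosis genes fell. Of 20 TGF-beta targets 11 rose, of 24 matrix genes 15 rose, and of 20 luminal epithelial genes 8 fell. The proliferation marker Mki67 fell from 862 ± 154 to 33.7 ± 7.7 CPM, a log2 fold change of -4.68 ± 0.47 (q = 1.7e-05). Ccn2, a matricellular TGF-beta target, rose from 137 ± 28 to 3471 ± 4.8 CPM, a log2 fold change of 4.66 ± 0.28 (q = 9.1e-07). The comparison asks how TGFb, which arrests many epithelial cells and can make them mesenchymal, acts on cells with wild-type Pygo2.

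The 5 largest increases were genes at or near 0 counts before treatment. They were Tll1, a metalloprotease of the BMP1 family (0 to 84.6 ± 9.7 CPM, at least 1331-fold, q = 1.9e-06), the growth factor Igf1 (0 to 51.2 ± 12 CPM, at least 802-fold, q = 8.1e-07) and the cadherin Cdh10 (0 to 45.9 ± 7.6 CPM, at least 721-fold, q = 1.0e-04). Next came the TNF receptor family member Cd40 (0.0236 ± 0.033 to 108 ± 5.3 CPM, 5121-fold with an interval of 919 to 202308, q = 5.1e-06) and the complement protease Masp1 (0.0191 ± 0.027 to 89.5 ± 2.7 CPM, 4243-fold with an interval of 761 to 167617, q = 3.7e-06). Bounds beside a group at 0 counts are taken against 3 counts over that group, and intervals are 95% counting intervals, which cover counting error only. The 5 largest decreases were the keratin Krt79 (10.7 ± 0.96 to 0 CPM, at least 153-fold, q = 3.1e-06), the aspartoacylase Aspa (6.4 ± 1.4 to 0 CPM, at least 92.3-fold, q = 4.7e-05) and the sulfotransferase Chst1 (5.08 ± 0.055 to 0 CPM, at least 72.3-fold, q = 7.9e-05). Next came the kallikrein protease Klk10 (73.4 ± 0.71 to 0.186 ± 0.054 CPM, q = 1.6e-06) and Krt6a (15.5 ± 0.087 to 0.0470 ± 0.0030 CPM, 331-fold with an interval of 91.3 to 2738, q = 2.4e-05). Krt6a shares reads with its near-identical copy Krt6b, so its level is uncertain.

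Of 20 TGF-beta targets, 11 rose and 9 did not pass (adjusted over the list alone, 12 up, camera adjusted p = 1.0e-06, adjusted p = 0.14 with an estimated correlation). The matrix protein Postn rose from 13.5 ± 1.1 to 476 ± 52 CPM (q = 1.3e-06). Among 4 Id genes, inhibitors of basic helix-loop-helix factors, 2 fell and 2 did not pass (adjusted over the list alone, 2 down, camera adjusted p = 0.0086, adjusted p = 0.14 with an estimated correlation). Id4 fell from 80.5 ± 19 to 6.11 ± 0.19 CPM (q = 2.1e-05). Id2 fell from 242 ± 38 to 28 ± 4.8 CPM (q = 1.1e-04). In the mesenchymal list (25 genes), 13 rose, 4 fell and 8 did not pass (adjusted over the list alone, 14 up and 4 down, camera adjusted p = 1.7e-04, adjusted p = 0.24 with an estimated correlation). Vim, the intermediate filament of mesenchymal cells, rose from 21.7 ± 1.7 to 647 ± 55 CPM (q = 2.4e-06). Of 29 epithelial genes, 9 fell and 20 did not pass (adjusted over the list alone, 9 down, camera adjusted p = 0.0086, adjusted p = 0.64 with an estimated correlation). Ovol1, a repressor of mesenchymal programmes, went from 11.0 ± 1.3 to 0.0716 ± 0.038 CPM, 155-fold with an interval of 52.6 to 753 (q = 5.3e-06). The tight junction gene Ocln fell from 33.1 ± 3.1 to 8.06 ± 1.9 CPM (q = 1.3e-04).

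Of 24 collagen and matrix genes, 15 rose, 3 fell and 6 did not pass (adjusted over the list alone, 17 up and 3 down, camera adjusted p = 1.7e-04, adjusted p = 0.37 with an estimated correlation). Col12a1 rose from 36.5 ± 1.1 to 779 ± 47 CPM (q = 3.7e-05). The fibrillar collagen Col3a1 went from 0 to 1.11 ± 0.37 CPM, at least 17.4-fold (q = 2.7e-04). Among 17 actin and smooth muscle genes, 9 rose and 8 did not pass (adjusted over the list alone, 13 up, camera adjusted p = 0.0040, adjusted p = 0.58 with an estimated correlation). Smooth muscle actin Acta2 went from 0 to 3.65 ± 0.30 CPM, at least 57.8-fold (q = 3.2e-04). Tagln rose from 0.119 ± 0.10 to 1.61 ± 0.26 CPM (q = 0.0024). Actin genes share long stretches of sequence, which makes the levels of Acta2, Acta1 and Actg2 uncertain. Of 16 YAP and TEAD targets, 8 rose, 1 fell and 7 did not pass (adjusted over the list alone, 8 up and 1 down, camera adjusted p = 0.0040, adjusted p = 0.44 with an estimated correlation). Ankrd1 rose from 168 ± 43 to 758 ± 44 CPM (q = 0.0086). Of 20 luminal genes, 8 fell and 12 did not pass (adjusted over the list alone, 8 down, camera adjusted p = 0.0027, adjusted p = 0.051 with an estimated correlation). The prolactin receptor Prlr fell from 13.3 ± 2.2 to 0.497 ± 0.13 CPM (q = 3.2e-04).

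All 30 S phase genes fell, also when adjusted over the list alone (camera adjusted p = 6.3e-42, adjusted p = 0.010 with an estimated correlation). Cdc6, which loads the replicative helicase, fell from 69.2 ± 0.49 to 2.70 ± 0.074 CPM (q = 9.1e-07). Cyclin E2 (Ccne2) fell from 65.2 ± 6.3 to 2.32 ± 0.75 CPM (q = 4.0e-05). The 30 G2 and mitosis genes all fell too, and did so adjusted over the list alone (camera adjusted p = 5.0e-64, adjusted p = 0.010 with an estimated correlation), with cyclin A2 (Ccna2) down from 332 ± 44 to 11.3 ± 1.4 CPM (q = 6.2e-06). Among 19 cell cycle inhibitors and p53 targets, 9 rose, 1 fell and 9 did not pass (adjusted over the list alone, 9 up and 1 down, camera adjusted p = 0.0040, adjusted p = 0.073 with an estimated correlation). The stress gene Gadd45a rose from 4.71 ± 0.53 to 44.0 ± 0.69 CPM (q = 3.1e-06). Of 21 glycolysis and hypoxia genes, 1 rose, 7 fell and 13 did not pass (adjusted over the list alone, 1 up and 8 down, camera adjusted p = 0.0088, adjusted p = 0.37 with an estimated correlation). Ldha fell from 1526 ± 119 to 311 ± 15 CPM (q = 2.5e-04).

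Among 5 immune markers, 2 rose and 3 did not pass (adjusted over the list alone, 2 up, camera adjusted p = 0.39), with Fcer1g from 0.0943 ± 0.13 to 1.83 ± 0.68 CPM (q = 0.0032). Of 6 endothelial markers, 2 rose and 4 did not pass (adjusted over the list alone, 2 up and 1 down, camera adjusted p = 0.21), with Erg from 0.0618 ± 0.021 to 3.02 ± 0.10 CPM, 47.8-fold with an interval of 16 to 235 (q = 9.0e-04). Of 11 fibroblast markers, 4 rose, 1 fell and 6 did not pass (adjusted over the list alone, 4 up and 1 down, camera adjusted p = 0.39). Lsp1 rose from 5.57 ± 1.1 to 41.6 ± 5.9 CPM (q = 0.0046). Cd34 fell from 8.42 ± 1.2 to 1.31 ± 0.018 CPM (q = 7.6e-04). Of 3 adipocyte markers, 0 passed the quasi-likelihood test of edgeR (0 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.67). Among 28 ribosomal protein genes, which share reads with processed pseudogenes, 1 fell and 27 did not pass (adjusted over the list alone, 0, camera adjusted p = 0.096), Rps6, from 854 ± 27 to 497 ± 16 CPM (q = 0.044).

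With the GC content and length correction TGFb changed 6004 genes in WT, 2986 higher and 3018 lower. With total-count scaling 1592 were higher and 2033 lower. Without 1 library the count was 2101 or 2299 (untreated replicate 1 or 2 left out) and 2363 or 2137 (treated replicate 1 or 2). Lsp1, Rps6 and Ankrd1 each failed to pass in at least 1 of these fits, as Tagln and Rps6 did under other settings.

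In the AE line TGFb changed 1371 genes, 802 higher and 569 lower. Of 25 mesenchymal genes 13 rose, of 4 milk genes 3 fell, and 20 of 30 genes fell in both the S phase and the G2 and mitosis list. Tnc (tenascin C) rose from 276 ± 18 to 3047 ± 183 CPM, a log2 fold change of 3.47 ± 0.50 (q = 0.0014). The stem cell factor receptor Kit, a marker of luminal progenitors, fell from 422 ± 17 to 29.4 ± 1.1 CPM, a log2 fold change of -3.84 ± 0.28 (q = 5.5e-05).

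The 5 largest increases were Cd40 (0.291 ± 0.10 to 74.9 ± 5.0 CPM, q = 7.7e-05), Pappa2, a protease of IGF-binding proteins (0.0364 ± 0.051 to 10.8 ± 0.34 CPM, 267-fold with an interval of 73.5 to 2209, q = 5.1e-04) and the metalloprotease Adamts16 (0.0409 ± 0.0064 to 5.34 ± 1.1 CPM, 132-fold with an interval of 36.2 to 1097, q = 6.1e-04). Next came the T-type calcium channel Cacna1g (0.100 ± 0.013 to 8.36 ± 0.19 CPM, q = 7.1e-05) and the polysialyltransferase St8sia2 (0.232 ± 0.12 to 17.3 ± 2.2 CPM, q = 0.0034). The 5 largest decreases were Sostdc1, a secreted BMP and Wnt antagonist (7.60 ± 1.0 to 0.191 ± 0.089 CPM, q = 0.0054), the coronin Coro2a (186 ± 2.1 to 5.11 ± 0.38 CPM, q = 5.7e-05) and the lipase family member Lipk (22.0 ± 0.66 to 0.680 ± 0.18 CPM, q = 4.9e-05). Next came the metalloreductase Steap4 (196 ± 12 to 9.27 ± 1.3 CPM, q = 6.3e-04) and Prlr (29.2 ± 2.4 to 1.40 ± 0.29 CPM, q = 0.0015).

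Of 20 TGF-beta targets, 6 rose and 14 did not pass (adjusted over the list alone, 11 up, camera adjusted p = 9.5e-08, adjusted p = 0.072 with an estimated correlation). The CDK inhibitor Cdkn2b rose from 5.98 ± 0.55 to 58.6 ± 6.4 CPM (q = 2.8e-05). Ccn2 rose from 259 ± 0.23 to 702 ± 18 CPM (q = 0.0035). Of 4 Id genes, 1 fell and 3 did not pass (adjusted over the list alone, 2 down, camera adjusted p = 0.092), Id2, from 328 ± 12 to 97.3 ± 2.7 CPM (q = 0.011). In the mesenchymal list, 13 rose and 12 did not pass (adjusted over the list alone, 17 up, camera adjusted p = 1.1e-11, adjusted p = 0.035 with an estimated correlation). The gelatinase Mmp2 rose from 0.777 ± 0.39 to 14.3 ± 0.97 CPM (q = 0.0015). Of 29 epithelial genes, 3 fell and 26 did not pass (adjusted over the list alone, 3 down, camera adjusted p = 0.13), and the tight junction gene Tjp3 fell from 15.1 ± 2.1 to 2.76 ± 0.95 CPM (q = 0.0066). Among 24 matrix genes, 13 rose, 2 fell and 9 did not pass (adjusted over the list alone, 16 up and 3 down, camera adjusted p = 1.2e-05, adjusted p = 0.22 with an estimated correlation). Thbs1 (thrombospondin 1) rose from 837 ± 41 to 5740.0 ± 189 CPM (q = 0.021). Col1a2 rose from 49.2 ± 1.8 to 200.3 ± 15 CPM (q = 0.0048). Of 17 actin genes, 0 passed the quasi-likelihood test of edgeR (3 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.90). The actin list's median and mean lay above 0 while its test pointed down.

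Luminal genes (20 tested) moved down as a group, where 1 rose, 5 fell and 14 did not pass (adjusted over the list alone, 1 up and 8 down, camera adjusted p = 9.5e-08, adjusted p = 0.0038 with an estimated correlation). Aldh1a3, which marks luminal progenitors, fell from 54.2 ± 4.5 to 2.64 ± 0.19 CPM (q = 3.7e-05). Amphiregulin (Areg) rose from 0.646 ± 0.013 to 8.51 ± 0.52 CPM (q = 0.042). Of 4 milk genes, 3 fell and 1 did not pass (adjusted over the list alone, 3 down, camera adjusted p = 6.9e-11, adjusted p = 0.0033 with an estimated correlation). Kappa-casein (Csn3) fell from 153 ± 6.6 to 15.3 ± 0.70 CPM (q = 6.1e-05). Butyrophilin (Btn1a1) fell from 42.4 ± 0.71 to 5.06 ± 1.0 CPM (q = 3.7e-05). In the S phase list of 30, 20 fell and 10 did not pass (adjusted over the list alone, 27 down, camera adjusted p = 1.3e-20, adjusted p = 0.027 with an estimated correlation), with Uhrf1, a co-factor of maintenance DNA methylation, down from 76.8 ± 8.1 to 22.5 ± 2.2 CPM (q = 3.1e-04) and the helicase subunit Mcm6 from 200.2 ± 8.0 to 62.0 ± 1.2 CPM (q = 0.0012). Among 30 G2 and mitosis genes, 20 fell and 10 did not pass (adjusted over the list alone, 30 down, camera adjusted p = 7.9e-19, adjusted p = 0.072 with an estimated correlation), with survivin (Birc5) down from 214 ± 5.3 to 76.5 ± 3.1 CPM (q = 0.0036) and Ccna2 from 249 ± 2.2 to 89.9 ± 4.2 CPM (q = 0.023). Of 19 cell cycle inhibitors and p53 targets, 7 rose, 1 fell and 11 did not pass (adjusted over the list alone, 12 up and 1 down, camera adjusted p = 2.2e-06, adjusted p = 0.0082 with an estimated correlation). Gadd45a rose from 8.07 ± 0.73 to 68.4 ± 0.87 CPM (q = 3.7e-05). The p21 gene Cdkn1a rose from 67.8 ± 3.1 to 317 ± 6.3 CPM (q = 4.7e-04).

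Of 20 inflammatory genes, 6 rose, 1 fell and 13 did not pass (adjusted over the list alone, 8 up and 2 down, camera adjusted p = 0.019, adjusted p = 0.38 with an estimated correlation). Il6 rose from 0.286 ± 0.045 to 6.06 ± 0.79 CPM (q = 0.0012). Cyclooxygenase 2 (Ptgs2) rose from 12.8 ± 1.0 to 81.3 ± 7.7 CPM (q = 0.010). Of 19 cholesterol synthesis genes, 3 rose and 16 did not pass (adjusted over the list alone, 6 up, camera adjusted p = 0.022, adjusted p = 0.072 with an estimated correlation). Msmo1 rose from 41.3 ± 5.4 to 75.4 ± 0.42 CPM (q = 0.026). Of 5 immune markers, 0 passed the quasi-likelihood test of edgeR (3 at an unadjusted p under 0.05, 3 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.072 with an estimated correlation), with S100a8 from 0.714 ± 0.17 to 2.45 ± 0.34 CPM (q = 0.078). Of 6 endothelial markers, 0 passed the quasi-likelihood test of edgeR (3 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.49), with Erg from 46.7 ± 1.4 to 143 ± 4.7 CPM (q = 0.069). Of 11 fibroblast markers, 4 rose, 1 fell and 6 did not pass (adjusted over the list alone, 5 up and 2 down, camera adjusted p = 0.25). Lsp1 rose from 2.20 ± 0.17 to 46.2 ± 1.0 CPM (q = 0.0020). Col14a1 fell from 74.6 ± 0.67 to 5.66 ± 1.2 CPM (q = 3.4e-04). Of 3 adipocyte markers, 0 passed the quasi-likelihood test of edgeR (1 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.25). Of 28 ribosomal protein genes, 0 passed the quasi-likelihood test of edgeR (0 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.16).

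The GC content and length correction gave 3206 genes in AE, of which 1478 were higher and 1728 lower, so that the higher share moved from 58.5% to 46.1%. The 4-day libraries alone gave 4517. A fit of the 2 groups alone gave 6944, above the 5419 of TGFb in WT, which turns the order of the lines. Without 1 library the count was 352 or 404 (untreated replicate 1 or 2 left out) and 459 or 396 (treated replicate 1 or 2). In these fits 12 of the 34 named genes failed to pass at least once, among them Id2, Thbs1, Areg, Ccna2 and Msmo1 in all 4. Erg and S100a8 passed under several settings, among them DESeq2 and a replicate block within each line.

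The TGFb response differed between the lines for 1163 genes, 664 with a higher and 499 with a lower change in AE than in WT. The change in every one of the 30 G2 and mitosis genes was less negative in AE. Ccn2 went from 137 ± 28 to 3471 ± 4.8 CPM in WT and 259 ± 0.23 to 702 ± 18 in AE (difference -3.22 ± 0.35, q = 2.2e-04). This interaction asks whether cells with the altered PHD finger answer TGFb as wild-type cells do.

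The 5 genes with the most positive difference were led by Krt79, which went from 10.7 ± 0.96 to 0 CPM in WT and 3.75 ± 0.30 to 7.08 ± 1.1 in AE (q = 3.7e-05). Hhip, an antagonist of hedgehog ligands, went from 33.6 ± 1.4 to 0.262 ± 0.12 CPM in WT and 0.205 ± 0.032 to 3.96 ± 0.68 in AE (difference 11.24 ± 0.91, q = 3.7e-05). Dio2, which activates thyroid hormone, went from 3.23 ± 0.30 to 0.0720 ± 0.038 CPM in WT and 3.10 ± 0.85 to 165 ± 11 in AE (q = 0.0015). The desmosomal cadherin Dsg3 went from 65.7 ± 1.9 to 2.59 ± 0.37 CPM in WT and 0.205 ± 0.032 to 12.3 ± 2.0 in AE (difference 10.55 ± 1.31, q = 4.6e-04). The aldehyde dehydrogenase Aldh3a1 went from 102 ± 14 to 1.43 ± 0.074 CPM in WT and 0.127 ± 0.077 to 2.04 ± 0.0090 in AE (difference 10.16 ± 1.07, q = 1.7e-04). At the other end, Tll1 went from 0 to 84.6 ± 9.7 CPM in WT and 8.95 ± 0.77 to 22.5 ± 1.1 in AE (q = 6.8e-05). Igf1 went from 0 to 51.2 ± 12 CPM in WT and 298 ± 2.3 to 599 ± 39.9 in AE (q = 2.9e-05). Csn3 went from 0.0190 ± 0.027 to 2.00 ± 0.029 CPM in WT and 153 ± 6.6 to 15.3 ± 0.70 in AE (q = 2.9e-05). Thyroglobulin (Tg) went from 0 to 14.9 ± 0.69 CPM in WT and 2.87 ± 1.0 to 12.7 ± 0.52 in AE (q = 9.0e-04). Acta2 went from 0 to 3.65 ± 0.30 CPM in WT and 66.1 ± 3.4 to 79.4 ± 7.2 in AE (q = 0.0037). No fitted difference is given for genes with 3 or fewer counts in a group.

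Of 20 TGF-beta targets, 3 had a lower change in AE and 17 did not pass (adjusted over the list alone, 5 lower, camera adjusted p = 0.015, adjusted p = 0.64 with an estimated correlation). Postn went from 13.5 ± 1.1 to 476 ± 52 CPM in WT and 824 ± 32 to 1263 ± 19 in AE (difference -4.53 ± 0.42, q = 7.8e-05). Of 4 Id genes, 1 had a higher change in AE and 3 did not pass (adjusted over the list alone, 2 higher, camera adjusted p = 0.11), Id4, which went from 80.5 ± 19 to 6.11 ± 0.19 CPM in WT and 33.1 ± 2.1 to 46.1 ± 1.1 in AE (difference 4.2 ± 0.51, q = 4.1e-04). In the mesenchymal list, 4 had a higher change in AE, 3 had a lower one and 18 did not pass (adjusted over the list alone, 8 higher and 6 lower, camera adjusted p = 0.79). Vim went from 21.7 ± 1.7 to 647 ± 55 CPM in WT and 1123 ± 103 to 692 ± 9.5 in AE (difference -5.60 ± 0.46, q = 3.8e-05). The homeobox gene Prrx1 went from 12.4 ± 2.2 to 1.02 ± 0.36 CPM in WT and 2.66 ± 0.55 to 7.15 ± 1.5 in AE (difference 5.03 ± 0.46, q = 6.8e-05). Of 29 epithelial genes, 3 had a higher change in AE and 26 did not pass (adjusted over the list alone, 3 higher, camera adjusted p = 0.0496, adjusted p = 0.73 with an estimated correlation). Ovol1 went from 11.0 ± 1.3 to 0.0720 ± 0.038 CPM in WT and 3.21 ± 0.35 to 1.02 ± 0.30 in AE (q = 7.8e-04). The tricellular junction gene Marveld2 went from 46.1 ± 3.8 to 14.8 ± 0.090 CPM in WT and 16 ± 0.82 to 13.4 ± 1.3 in AE (difference 1.37 ± 0.30, q = 0.014). Of 24 matrix genes, 3 had a higher change in AE, 6 had a lower one and 15 did not pass (adjusted over the list alone, 4 higher and 8 lower, camera adjusted p = 0.0496, adjusted p = 0.73 with an estimated correlation). Col12a1 went from 36.5 ± 1.1 to 779 ± 47 CPM in WT and 276 ± 17 to 957 ± 39.7 in AE (difference -2.62 ± 0.61, q = 0.018). Of 17 actin genes, 2 had a lower change in AE and 15 did not pass (adjusted over the list alone, 5 lower, camera adjusted p = 6.1e-04, adjusted p = 0.64 with an estimated correlation), with Csrp1 from 166 ± 7.5 to 342.5 ± 17 CPM in WT and 246 ± 2.5 to 129 ± 5.2 in AE (difference -1.97 ± 0.49, q = 0.025).

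Of 30 S phase genes, 20 had a higher change in AE and 10 did not pass (adjusted over the list alone, 26 higher, camera adjusted p = 1.9e-22, adjusted p = 0.045 with an estimated correlation). Ccne2 went from 65.2 ± 6.3 to 2.32 ± 0.75 CPM in WT and 31.3 ± 2.1 to 13.2 ± 0.45 in AE (difference 3.57 ± 0.67, q = 0.0056). Cdc6 went from 69.2 ± 0.49 to 2.70 ± 0.074 CPM in WT and 38.1 ± 2.9 to 12.2 ± 0.19 in AE (difference 3.04 ± 0.36, q = 3.5e-04). All 30 G2 and mitosis genes passed, also adjusted over the list alone (camera adjusted p = 1.3e-53, adjusted p = 0.037 with an estimated correlation). Topoisomerase Top2a went from 1326 ± 161 to 55.7 ± 11 CPM in WT and 459.7 ± 7.0 to 239.8 ± 8.4 in AE (difference 3.64 ± 0.56, q = 0.0015). Mki67 went from 862 ± 154 to 33.7 ± 7.7 CPM in WT and 615 ± 21 to 245 ± 8.5 in AE (difference 3.35 ± 0.58, q = 0.0036). Of 4 milk genes, 2 had a lower change in AE and 2 did not pass (adjusted over the list alone, 1 higher and 2 lower, camera adjusted p = 0.0027, adjusted p = 0.064 with an estimated correlation), with Btn1a1 from 56.4 ± 1.9 to 16.8 ± 0.017 CPM in WT and 42.4 ± 0.71 to 5.06 ± 1.0 in AE (difference -1.32 ± 0.31, q = 0.021). Of 19 cholesterol synthesis genes, 1 had a higher change in AE and 18 did not pass (adjusted over the list alone, 1 higher, camera adjusted p = 0.0496, adjusted p = 0.19 with an estimated correlation), with Dhcr7 from 198 ± 11 to 63.7 ± 5.2 CPM in WT and 52.0 ± 4.0 to 45.4 ± 0.43 in AE (difference 1.44 ± 0.32, q = 0.014).

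The GC content and length correction gave 2595 genes, 1282 higher and 1313 lower. The 4-day libraries alone gave 1883 and 2007. Leaving out 1 library gave 653 and 715 genes (untreated WT replicate 1 and 2), 717 and 653 (TGFb-treated WT), 640 and 637 (untreated AE) and 669 and 656 (TGFb-treated AE). Marveld2, Col12a1, Csrp1, Btn1a1 and Dhcr7 were lost in at least 1 of these fits, and Acta2 with limma on log2(CPM + 1).

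**Figure D3:**
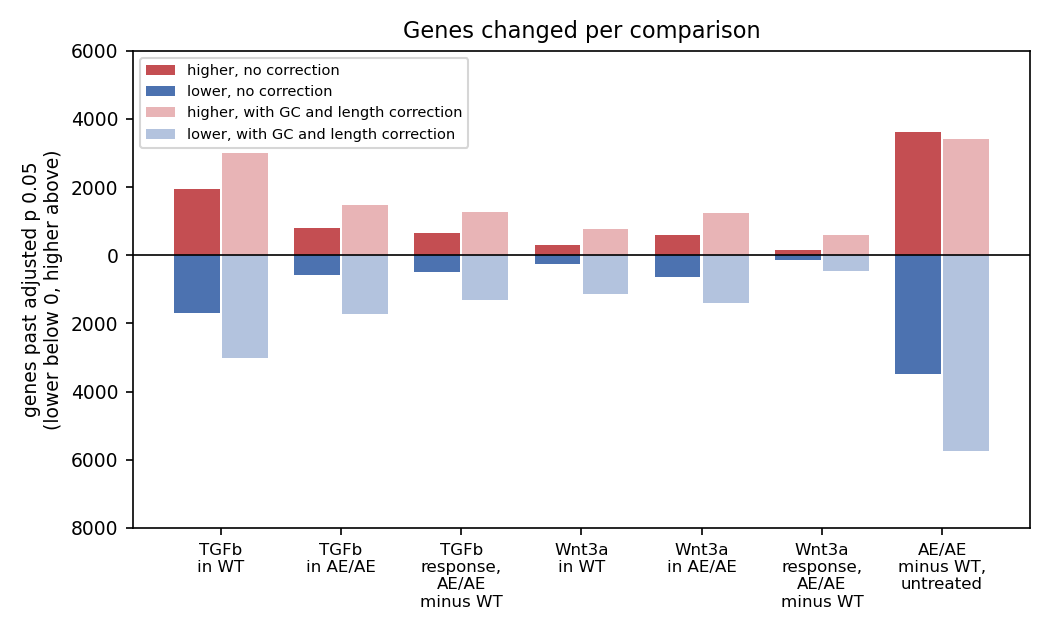
Number of genes changed (adjusted p below 0.05) in each comparison, higher above the zero line and lower below it, in dark bars without and in pale bars with the GC content and length correction.

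**Figure D4:**
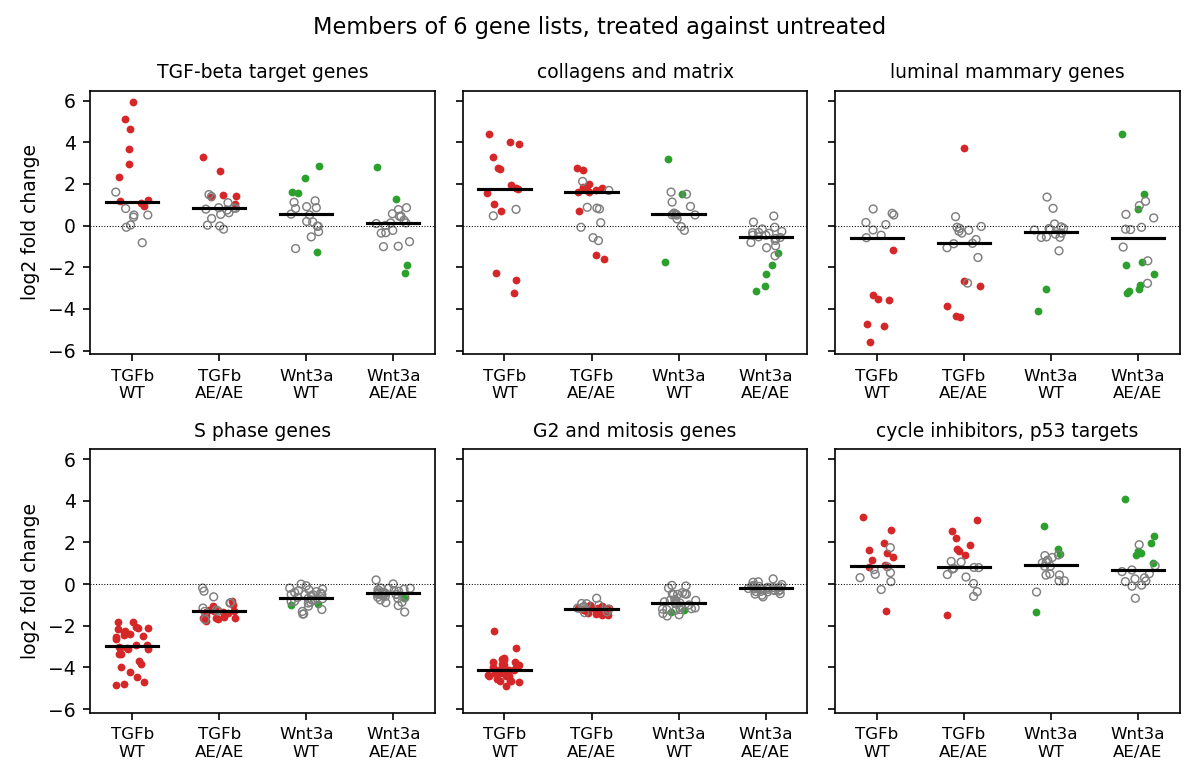
Log2 fold change (y axis) of members of selected gene lists in the treatment comparisons, 1 point per gene, with filled points past the adjusted p of 0.05, open grey points not past it and a bar at the median of the points shown. Of 572 points 540 are shown, and 32 with 3 or fewer counts in a group are left out.

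In the WT line Wnt3a changed 564 genes, 298 higher and 266 lower. Axin2, the general feedback target of beta-catenin, rose from 0.220 ± 0.096 to 97.4 ± 35 CPM, a log2 fold change of 8.73 ± 0.51 (q = 5.9e-06). Hey1, a Notch target, fell from 32.0 ± 3.4 to 1.85 ± 0.16 CPM, a log2 fold change of -4.11 ± 0.24 (q = 5.9e-06). Of 19 cell cycle inhibitors and p53 targets 3 rose, and 2 of 30 genes fell in both the S phase and the G2 and mitosis list. The comparison asks which genes follow the Wnt pathway that Pygo2 serves. The spread was estimated from all 16 libraries, and with the 3-day libraries alone 20 genes passed. Among them were Axin2, Stra6, Fjx1, Gimap8, Hlf, Hey1, Cdkn2b and Col9a1. With a replicate block within each line, chosen after the data were seen, 2250 passed, and 14 S phase and 21 G2 and mitosis genes fell.

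The other leading increases were the retinol transporter Stra6 (0 to 93.2 ± 31 CPM, at least 1375-fold, q = 1.6e-04) and Fjx1 (0.0458 ± 0.0067 to 5.28 ± 1.7 CPM, 116-fold with an interval of 31.8 to 966, q = 3.5e-04). Next came the gelatinase Mmp9 (0.238 ± 0.16 to 20.1 ± 2.9 CPM, q = 0.0012) and the GTPase Gimap8 (0.0963 ± 0.078 to 8.0 ± 2.2 CPM, q = 1.6e-04). Decreases were led by the neutrophil chemokine Cxcl5 (201 ± 48 to 3.92 ± 2.8 CPM, q = 0.0031), the cartilage collagen Col9a1 (5.85 ± 2.7 to 0.177 ± 0.13 CPM, q = 5.1e-04) and the circadian PAR bZIP factor Hlf (23.3 ± 1.7 to 0.771 ± 0.018 CPM, q = 1.4e-04). Next came Kank4 (7.25 ± 5.9 to 0.333 ± 0.29 CPM, q = 0.0032) and Hey1.

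Of 21 canonical Wnt targets, 2 rose, 1 fell and 18 did not pass (adjusted over the list alone, 9 up and 2 down, camera adjusted p = 0.0046, adjusted p = 0.24 with an estimated correlation). Beside Axin2, the ubiquitin ligase Rnf43, a feedback inhibitor of Wnt receptors, rose from 0.878 ± 0.39 to 4.30 ± 0.15 CPM (q = 0.0027). Bambi fell from 3.17 ± 0.59 to 1.52 ± 0.13 CPM (q = 0.035). Of 30 Wnt pathway components, 3 fell and 27 did not pass (adjusted over the list alone, 2 up and 3 down, camera adjusted p = 0.26). The receptor Fzd7 fell from 238 ± 32 to 85.6 ± 5.7 CPM (q = 0.0027). The secreted antagonist Sfrp1 fell from 310.0 ± 13 to 163 ± 46 CPM (q = 0.032). Of 20 TGF-beta targets, 4 rose, 1 fell and 15 did not pass (adjusted over the list alone, 4 up and 1 down, camera adjusted p = 0.011, adjusted p = 0.46 with an estimated correlation). Cdkn2b rose from 12.9 ± 1.1 to 94.5 ± 9.2 CPM (q = 7.5e-05). Ccn2 rose from 185 ± 16 to 542 ± 103 CPM (q = 0.0045). Of 24 matrix genes, 2 rose, 1 fell and 21 did not pass (adjusted over the list alone, 3 up and 1 down, camera adjusted p = 0.031, adjusted p = 0.60 with an estimated correlation). Fbln2 rose from 0.764 ± 0.081 to 7.05 ± 2.8 CPM (q = 0.012). Fbln1 fell from 2.59 ± 0.52 to 0.773 ± 0.17 CPM (q = 0.048).

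Of 20 luminal genes, 2 fell and 18 did not pass (adjusted over the list alone, 1 up and 2 down, camera adjusted p = 0.038, adjusted p = 0.24 with an estimated correlation), Hey1 and Prlr, from 33.5 ± 11 to 4.00 ± 4.1 CPM (q = 0.013). Of 30 S phase genes, 2 fell and 28 did not pass (adjusted over the list alone, 15 down, camera adjusted p = 1.8e-07, adjusted p = 0.25 with an estimated correlation), Clspn and Uhrf1, the latter from 155 ± 4.5 to 79.8 ± 2.6 CPM (q = 0.017). Of 30 G2 and mitosis genes, 2 fell and 28 did not pass (adjusted over the list alone, 21 down, camera adjusted p = 3.6e-11, adjusted p = 0.29 with an estimated correlation), Anln and the kinetochore gene Ndc80, the latter from 102 ± 38 to 39.7 ± 8.5 CPM (q = 0.024). Of 19 cell cycle inhibitors and p53 targets, 3 rose, 1 fell and 15 did not pass (adjusted over the list alone, 8 up and 1 down, camera adjusted p = 1.4e-04, adjusted p = 0.065 with an estimated correlation). Cdkn1a rose from 150.1 ± 2.4 to 412 ± 73 CPM (q = 0.0093) and Gadd45a from 7.59 ± 1.6 to 24.3 ± 1.2 CPM (q = 0.0024), and the p27 gene Cdkn1b fell from 167 ± 69 to 64.9 ± 6.4 CPM (q = 0.033). Of 22 chromatin regulators, 0 passed the quasi-likelihood test of edgeR (5 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.46 with an estimated correlation).

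Of 5 immune markers, 0 passed the quasi-likelihood test of edgeR (2 at an unadjusted p under 0.05, 2 adjusted over the list alone, camera adjusted p = 0.053), with S100a8 from 1.85 ± 1.8 to 7.47 ± 0.094 CPM (q = 0.058). Of 6 endothelial markers, 0 passed the quasi-likelihood test of edgeR (1 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.47). Of 11 fibroblast markers, 2 fell and 9 did not pass (adjusted over the list alone, 2 up and 2 down, camera adjusted p = 0.53), Pdgfra and Cd34, the latter from 5.77 ± 1.1 to 1.21 ± 0.24 CPM (q = 0.013). The fibroblast list's median was 0 and its mean and test lay below 0. Of 3 adipocyte markers, 0 passed the quasi-likelihood test of edgeR (1 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.46). Of 28 ribosomal protein genes, 0 passed the quasi-likelihood test of edgeR (0 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.60 with an estimated correlation).

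The GC content and length correction gave 1904 genes, 781 higher and 1123 lower (a higher share of 41.0% against 52.8%), and 260 with the 3-day libraries alone. With total-count scaling 353 were higher and 225 lower. Without 1 library the count was 346 or 2646 (untreated replicate 1 or 2 left out) and 3139 (1232 higher and 1907 lower) or 281 (191 and 90) without Wnt3a-treated replicate 1 or 2. Fbln2, Fbln1, Bambi, Sfrp1, Prlr, Uhrf1, Ndc80, Cdkn1b, Cdkn1a and Cd34 were lost in at least 1 of these fits, and S100a8 passed in all but the last, with DESeq2 and with a block within each line, among others.

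In the AE line Wnt3a changed 1229 genes, 604 higher and 625 lower. Of 21 canonical Wnt targets 8 rose, of 4 milk genes 3 fell, and of 19 cell cycle inhibitors and p53 targets 7 rose. Axin2 rose from 2.94 ± 0.59 to 76.6 ± 19.8 CPM, a log2 fold change of 4.70 ± 0.40 (q = 3.0e-05). Csn3 fell from 563 ± 111 to 8.50 ± 1.3 CPM, a log2 fold change of -6.05 ± 0.35 (q = 3.5e-06). With the 3-day libraries alone 357 genes passed.

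The 5 largest increases were Cyp4f39, a fatty acid hydroxylase (0 to 20.6 ± 0.081 CPM, at least 337-fold, q = 3.1e-05), the enamel protease Mmp20 (0 to 5.21 ± 1.2 CPM, at least 84.6-fold, q = 0.0014) and Stra6 (0.144 ± 0.15 to 126 ± 21 CPM, q = 6.1e-05). Next came Gimap8 (0.0409 ± 0.00057 to 29.8 ± 1.9 CPM, 729.7-fold with an interval of 202 to 6031, q = 1.6e-05) and the proteoglycan decorin, Dcn (0.0206 ± 0.029 to 5.92 ± 6.5 CPM, 283-fold with an interval of 50.5 to 11232, q = 0.0036). Decreases were led by the protease inhibitor A2m (29.3 ± 15 to 0.162 ± 0.063 CPM, q = 1.6e-04) and the casein Csn1s1 (9.22 ± 4.5 to 0.0828 ± 0.12 CPM, q = 0.0018). Next came Csn3, Brinp1 (44.5 ± 11 to 0.702 ± 0.057 CPM, q = 4.3e-05) and the cartilage protein Ucma (47.2 ± 35 to 0.800 ± 0.80 CPM, q = 0.0016).

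Of 21 canonical Wnt targets, 8 rose, 1 fell and 12 did not pass (adjusted over the list alone, 10 up and 1 down, camera adjusted p = 8.0e-06, adjusted p = 0.016 with an estimated correlation). Beside Axin2, the receptor Tnfrsf19 rose from 1.41 ± 0.57 to 50.5 ± 3.2 CPM (q = 5.3e-04). Nkd2, an inhibitor of dishevelled, rose from 81.0 ± 48 to 350.1 ± 2.1 CPM (q = 0.0018). Of 30 Wnt components, 4 rose, 4 fell and 22 did not pass (adjusted over the list alone, 4 up and 6 down, camera adjusted p = 0.38). The ligand Wnt6 rose from 0 to 3.98 ± 0.78 CPM, at least 65.3-fold (q = 0.0039). Sfrp1 fell from 205 ± 36 to 52.1 ± 6.9 CPM (q = 1.5e-04). The components' mean lay above 0 and their median and test below.

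Of 20 luminal genes, 3 rose, 7 fell and 10 did not pass (adjusted over the list alone, 3 up and 10 down, camera adjusted p = 4.4e-04, adjusted p = 0.016 with an estimated correlation). Hey1 fell from 175 ± 4.8 to 18.6 ± 3.8 CPM (q = 1.2e-05) and Aldh1a3 from 29.9 ± 3.1 to 3.57 ± 1.4 CPM (q = 1.3e-04), and Ly6d rose from 0.122 ± 0.056 to 2.67 ± 1.9 CPM (q = 0.042). Of 4 milk genes, 3 fell and 1 did not pass (adjusted over the list alone, 3 down, camera adjusted p = 7.1e-14, adjusted p = 0.0011 with an estimated correlation), with Btn1a1 from 83.4 ± 2.2 to 23.2 ± 1.3 CPM (q = 3.0e-04). Of 24 matrix genes, 1 rose, 5 fell and 18 did not pass (adjusted over the list alone, 1 up and 7 down, camera adjusted p = 0.0025, adjusted p = 0.42 with an estimated correlation). The basement membrane collagen Col4a1 fell from 504 ± 70.3 to 66.5 ± 5.7 CPM (q = 8.8e-05). Of 30 S phase genes, 1 fell and 29 did not pass (adjusted over the list alone, 0, camera adjusted p = 0.0025, adjusted p = 0.42 with an estimated correlation), Uhrf1, from 62.5 ± 3.1 to 39.0 ± 9.2 CPM (q = 0.047). Of 19 cell cycle inhibitors and p53 targets, 7 rose and 12 did not pass (adjusted over the list alone, 8 up, camera adjusted p = 2.9e-07, adjusted p = 0.0040 with an estimated correlation). Gadd45a rose from 11.6 ± 1.5 to 199 ± 56 CPM (q = 5.5e-06), the p53 target Eda2r from 13.0 ± 2.9 to 64.8 ± 11 CPM (q = 0.0062) and Cdkn1a from 106 ± 48 to 415 ± 1.5 CPM (q = 6.5e-04). Of 19 cholesterol synthesis genes, 5 rose and 14 did not pass (adjusted over the list alone, 6 up, camera adjusted p = 0.0040, adjusted p = 0.040 with an estimated correlation). Idi1 rose from 24.7 ± 5.5 to 69.3 ± 7.3 CPM (q = 0.022). Cyp51 rose from 88.7 ± 5.4 to 179.6 ± 7.7 CPM (q = 0.0091).

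Of 5 immune markers, 1 rose and 4 did not pass (adjusted over the list alone, 1 up, camera adjusted p = 0.14), S100a8, from 1.84 ± 0.55 to 10.7 ± 1.3 CPM (q = 0.011). Of 6 endothelial markers, 1 fell and 5 did not pass (adjusted over the list alone, 2 down, camera adjusted p = 0.12), Flt1, from 13.7 ± 0.47 to 2.84 ± 0.57 CPM (q = 0.0012). Of 11 fibroblast markers, 2 rose, 3 fell and 6 did not pass (adjusted over the list alone, 2 up and 3 down, camera adjusted p = 0.11). Col14a1 fell from 37.9 ± 14 to 0.922 ± 0.13 CPM (q = 5.7e-05). Of 3 adipocyte markers, 1 fell and 2 did not pass (adjusted over the list alone, 1 down, camera adjusted p = 0.14), Fabp4, from 2.31 ± 0.34 to 0.486 ± 0.19 CPM (q = 0.016). Of 28 ribosomal protein genes, 0 passed the quasi-likelihood test of edgeR (1 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.24).

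The GC content and length correction gave 2626 genes. Without Wnt3a-treated replicate 1 or 2 the count was 577 or 655, and without untreated replicate 2 it was 985, 387 higher and 598 lower. Without both high-Lars2 libraries it was 475, and Ly6d, Uhrf1, Idi1, Cyp51, S100a8, Eda2r and Fabp4 were lost without at least 1 library.

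**Figure D5:**
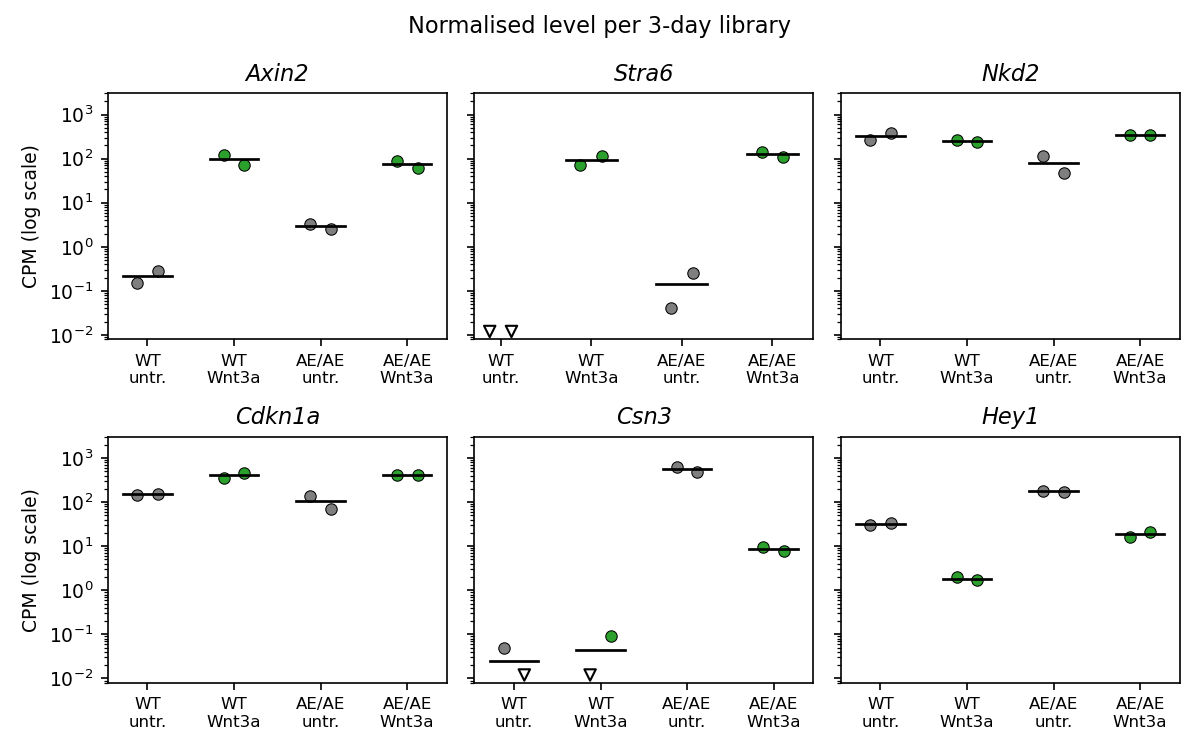
Levels of Axin2, Stra6, Nkd2, Cdkn1a, Csn3 and Hey1 (CPM, log axis) in the 8 libraries of the 3-day experiment, 1 point per library with lines at the group means and open triangles at the bottom for libraries with 0 counts.

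The Wnt3a response differed between the lines for 308 genes, 155 with a higher and 153 with a lower change in AE. Axin2 rose in both lines, and went from 0.220 ± 0.096 to 97.4 ± 35 CPM in WT and 2.94 ± 0.59 to 76.6 ± 19.8 in AE (difference -4.02 ± 0.60, q = 0.0054). Nkd2 went from 327 ± 81 to 250.2 ± 12 CPM in WT and 81.0 ± 48 to 350.1 ± 2.1 in AE (difference 2.50 ± 0.46, q = 0.017). Of 24 collagen and matrix genes 6 had a lower change in AE. With the 3-day libraries alone 8 genes passed, among them Igf1, Bcl11b, Col2a1 and Runx3, but neither Axin2 nor Nkd2. With replicate numbers crossed between the lines as a block, chosen after the data were seen, 709 passed (324 higher, 385 lower), and 1188 with a block within each line.

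The most positive differences were those of the growth factor homologue Fgf13, from 36.8 ± 13 to 22.0 ± 7.6 CPM in WT and 0 to 1.5 ± 0.14 in AE (q = 0.0029), and of Krt6b, from 6.07 ± 0.015 to 6.76 ± 3.6 CPM in WT and 0 to 0.993 ± 0.58 in AE (q = 0.036). Akr1c18, which inactivates progesterone, went from 5.86 ± 3.6 to 2.89 ± 0.20 CPM in WT and 0.0400 ± 0.057 to 2.85 ± 1.2 in AE (q = 0.0054). The transcription factor Bcl11b went from 6.65 ± 3.2 to 1.74 ± 0.31 CPM in WT and 0.615 ± 0.30 to 18.8 ± 5.0 in AE (difference 6.85 ± 0.68, q = 8.6e-04). Runx3 went from 42.0 ± 0.54 to 40.1 ± 5.5 CPM in WT and 0.0210 ± 0.029 to 2.19 ± 0.060 in AE (q = 0.0029). The most negative were those of Igf1, from 0 to 0.530 ± 0.13 CPM in WT and 282 ± 91 to 43.5 ± 1.8 in AE (q = 0.0013), and Adamts17, from 0 to 0.222 ± 0.19 CPM in WT and 9.29 ± 5.0 to 0.925 ± 0.037 in AE (q = 0.0094). The sterol transporter Gramd1b went from 0 to 0.111 ± 0.033 CPM in WT and 8.03 ± 0.26 to 0.905 ± 0.0080 in AE (q = 0.0049). The cartilage collagen Col2a1 went from 0.112 ± 0.016 to 0.726 ± 0.14 CPM in WT and 131 ± 86 to 4.47 ± 1.6 in AE (difference -7.50 ± 0.86, q = 0.0014). Skeletal actin Acta1 went from 0.597 ± 0.20 to 7.55 ± 7.1 CPM in WT and 4.50 ± 5.1 to 0.358 ± 0.21 in AE (difference -7.26 ± 1.40, q = 0.020).

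Of 21 canonical Wnt targets, 2 had a higher change in AE, 1 had a lower one and 18 did not pass (adjusted over the list alone, 4 higher and 1 lower, camera adjusted p = 0.74). The receptor-degrading ligase Znrf3 went from 30.6 ± 2.1 to 25.9 ± 7.1 CPM in WT and 26.9 ± 2.1 to 57.5 ± 0.093 in AE (difference 1.34 ± 0.30, q = 0.039). Of 30 Wnt components, 1 had a higher change in AE and 29 did not pass (adjusted over the list alone, 3 higher and 4 lower, camera adjusted p = 0.97), Fzd7, which went from 238 ± 32 to 85.6 ± 5.7 CPM in WT and 191 ± 43 to 166 ± 40.0 in AE (difference 1.27 ± 0.30, q = 0.048). The Wnt target list's median lay below 0 and its mean and test above, and the components' mean lay above 0 and their median and test below. Of 24 matrix genes, 6 had a lower change in AE and 18 did not pass (adjusted over the list alone, 8 lower, camera adjusted p = 6.7e-06, adjusted p = 0.43 with an estimated correlation). Col4a1 went from 1.44 ± 0.46 to 2.14 ± 0.0050 CPM in WT and 504 ± 70.3 to 66.5 ± 5.7 in AE (difference -3.48 ± 0.43, q = 0.0029). Fbln2 went from 0.764 ± 0.081 to 7.05 ± 2.8 CPM in WT and 67.6 ± 54 to 24.8 ± 5.0 in AE (difference -4.64 ± 0.78, q = 0.011).

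Other lists passed as groups without a member that did. Of 17 actin genes, 0 passed the quasi-likelihood test of edgeR (5 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.90 with an estimated correlation). Of 30 G2 and mitosis genes, 0 passed the quasi-likelihood test of edgeR (4 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 3.1e-04, adjusted p = 0.79 with an estimated correlation). Of 20 unfolded protein response genes, 0 passed the quasi-likelihood test of edgeR (7 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.0073, adjusted p = 0.43 with an estimated correlation). Of 22 chromatin regulators, 0 passed the quasi-likelihood test of edgeR (3 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.49 with an estimated correlation).

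The GC content and length correction gave 1060 genes, and 146 with the 3-day libraries alone. Without 1 library the count was 144 or 114 (Wnt3a-treated AE replicate 1 or 2 left out), 1897 (Wnt3a-treated WT replicate 1, 1281 higher and 616 lower) and 1406 (untreated WT replicate 2, 550 and 856). Without both high-Lars2 libraries it was 106, and Krt6b, Acta1, Znrf3, Fzd7, Nkd2 and Fbln2 were lost without at least 1 library.

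Untreated AE and WT cells differed in 7082 of the 13172 genes tested, 3609 higher and 3473 lower in AE (n = 4 libraries per line, from both times). Of 24 matrix genes 19, of 20 luminal genes 12 and of 21 canonical Wnt targets 13 were higher in AE, and 24 of 30 S phase genes and 10 of 19 cholesterol synthesis genes were lower. Serpinf1, an inhibitor of vessel growth, was higher in AE, from 0.244 ± 0.13 to 152 ± 19 CPM, a log2 fold change of 9.29 ± 0.25 (q = 1.3e-10). Aggrecan (Acan), the proteoglycan of cartilage, was lower, from 519 ± 140.1 to 0.229 ± 0.10 CPM, a log2 fold change of -11.09 ± 0.25 (q = 6.9e-11).

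Genes seen almost only in AE were Igf1 (0 to 289.8 ± 53 CPM, at least 8835-fold, q = 1.5e-09), the collagen chain Col9a2 (0 to 187 ± 42 CPM, at least 5668-fold, q = 1.6e-08) and Kit (0.0118 ± 0.024 to 386 ± 52 CPM, 35379.7-fold with an interval of 6349.6 to 1397460.0, q = 1.3e-09). Next came the transcription factor Sox10 (0 to 154 ± 67 CPM, at least 4693-fold, q = 3.7e-07) and the collagen receptor chain Itga11 (0 to 136 ± 71 CPM, at least 4166-fold, q = 1.2e-06). Nearly absent from AE were the transcript U90926 (320.1 ± 106 to 0.0101 ± 0.020 CPM, 31247-fold with an interval of 5608 to 1234230.0, q = 3.1e-08) and the homeobox gene Nkx2-3 (22.4 ± 6.1 to 0 CPM, at least 750.5-fold, q = 9.0e-07). Next came Fgf13 (32.7 ± 9.2 to 0.00909 ± 0.018 CPM, 3167-fold with an interval of 568 to 125126, q = 3.2e-08) and Dynap (568 ± 124 to 0.274 ± 0.18 CPM, q = 8.3e-09).

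Of 24 matrix genes, 19 were higher, 2 were lower and 3 did not pass (adjusted over the list alone, 19 higher and 2 lower, camera adjusted p = 1.1e-10, adjusted p = 0.13 with an estimated correlation). An example was biglycan (Bgn, 0.0213 ± 0.025 to 101 ± 62 CPM, 4639-fold with an interval of 1284 to 38314, q = 1.0e-08). Of 17 actin and smooth muscle genes, 12 were higher, 4 were lower and 1 did not pass (adjusted over the list alone, 12 higher and 4 lower, camera adjusted p = 0.013, adjusted p = 0.76 with an estimated correlation), with Acta2 (0 to 72.5 ± 36 CPM, at least 2214-fold, q = 2.2e-07) and Tagln (0.0927 ± 0.067 to 17.4 ± 10.1 CPM, q = 2.0e-07) higher. Of 21 canonical Wnt targets, 13 were higher, 5 were lower and 3 did not pass (adjusted over the list alone, 13 higher and 5 lower, camera adjusted p = 0.0051, adjusted p = 0.13 with an estimated correlation). Nkd1 (0 to 8.13 ± 1.8 CPM, at least 248-fold, q = 2.4e-07) and the stem cell receptor Lgr5 (0 to 4.11 ± 0.91 CPM, at least 126-fold, q = 2.1e-06) were higher, and Notum was lower (6.60 ± 3.6 to 0.301 ± 0.40 CPM, q = 5.1e-04). Of 20 luminal genes, 12 were higher, 2 were lower and 6 did not pass (adjusted over the list alone, 13 higher and 2 lower, camera adjusted p = 4.5e-06, adjusted p = 0.014 with an estimated correlation). Foxa1 was higher (0.0583 ± 0.060 to 7.54 ± 1.7 CPM, q = 5.6e-07) and Areg was lower (358 ± 119.9 to 3.60 ± 6.0 CPM, q = 7.7e-06). Of 4 milk genes, 2 were higher, 1 was lower and 1 did not pass (adjusted over the list alone, 2 higher and 1 lower, camera adjusted p = 0.0066, adjusted p = 0.13 with an estimated correlation), with Csn3 (0.0222 ± 0.026 to 358 ± 245 CPM, 16365-fold with an interval of 4530.0 to 135138, q = 2.6e-10) higher and Xdh (52.5 ± 25 to 16.6 ± 6.9 CPM, q = 5.6e-04) lower.

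Of 30 S phase genes, 24 were lower and 6 did not pass (adjusted over the list alone, 24 lower, camera adjusted p = 0.0020, adjusted p = 0.54 with an estimated correlation). Ribonucleotide reductase Rrm2 stood lower in AE (350.5 ± 88 to 96.9 ± 14 CPM, q = 9.7e-06). Of 30 G2 and mitosis genes, 21 were lower and 9 did not pass (adjusted over the list alone, 23 lower, camera adjusted p = 0.0013, adjusted p = 0.74 with an estimated correlation), such as Top2a (1598 ± 552 to 470.1 ± 103 CPM, q = 2.1e-04). Of 19 cholesterol synthesis genes, 1 was higher, 10 were lower and 8 did not pass (adjusted over the list alone, 1 higher and 10 lower, camera adjusted p = 0.016, adjusted p = 0.13 with an estimated correlation), such as Dhcr7 (170.4 ± 45 to 51.8 ± 2.8 CPM, q = 3.2e-06).

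Of 5 immune markers, 1 was higher, 2 were lower and 2 did not pass (adjusted over the list alone, 1 higher and 2 lower, camera adjusted p = 0.95). Lyz2 was higher (0 to 1.12 ± 0.44 CPM, at least 33.8-fold, q = 6.9e-05) and Cd68 lower (3.99 ± 1.6 to 1.35 ± 0.38 CPM, q = 0.0045). The immune list's mean lay above 0 and its median and test below. Of 6 endothelial markers, 4 were higher, 1 was lower and 1 did not pass (adjusted over the list alone, 4 higher and 1 lower, camera adjusted p = 0.26), with Erg (0.0309 ± 0.038 to 35.8 ± 16 CPM, 1094-fold with an interval of 374 to 5309.8, q = 5.0e-07) higher and Pecam1 (0.894 ± 0.30 to 0.274 ± 0.22 CPM, q = 0.012) lower. Of 11 fibroblast markers, 7 were higher, 3 were lower and 1 did not pass (adjusted over the list alone, 7 higher and 3 lower, camera adjusted p = 0.0076, adjusted p = 0.16 with an estimated correlation). Col14a1 (0 to 56.2 ± 23 CPM, at least 1718-fold, q = 3.4e-08) was higher and Cd34 (7.09 ± 1.8 to 0.0407 ± 0.057 CPM, q = 2.5e-07) lower. Of 3 adipocyte markers, 1 was higher, 1 was lower and 1 did not pass (adjusted over the list alone, 1 higher and 1 lower, camera adjusted p = 0.72), with Fabp4 (0.125 ± 0.055 to 1.70 ± 0.74 CPM, q = 2.6e-05) higher and Pparg (2.20 ± 0.70 to 1.0 ± 0.95 CPM, q = 0.017) lower. Of 28 ribosomal protein genes, 6 were lower and 22 did not pass (adjusted over the list alone, 5 lower, camera adjusted p = 0.35), among them Rpl22 (299 ± 30.5 to 147 ± 22 CPM, q = 2.8e-04).

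The GC content and length correction gave 9167 genes, 3412 higher and 5755 lower in AE, so that the higher share moved from 51.0% to 37.2%, and it shifted the median log2 ratio of all genes by -0.23. In the all-library fit the untreated 4-day contrast gave 4583 genes. Cd68, Pecam1 and Pparg were lost in the 3-day one, and the last 2 without at least 1 library.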

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

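The tests of a lower starting level in AE and of differences between the lines other than Pygo2, and the GC content and length correction, were chosen after the results were seen. Apart from the last paragraph, the results in this part differed between the lines by the interaction test of edgeR, or of camera for gene lists. Groups of 2 libraries are too small to look for single outlying samples.

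The TGFb response differed for 1163 genes. The lists differed with an adjusted p of 0.0153 for TGF-beta targets, 0.0496 each for epithelial, matrix and cholesterol synthesis genes, 6.1e-04 for actin genes, 0.0027 for milk genes, 1.9e-22 for S phase genes and 1.3e-53 for G2 and mitosis genes. With an estimated correlation only the last 2 passed (adjusted p 0.045 and 0.037). Log2 differences (AE minus WT) were positive for Hhip (11.24), Dsg3 (10.55), Aldh3a1 (10.16), Prrx1 (5.03), Id4 (4.2), Top2a (3.64), Ccne2 (3.57), Mki67 (3.35), Cdc6 (3.04), Dhcr7 (1.44) and Marveld2 (1.37). They were negative for Vim (-5.60), Postn (-4.53), Ccn2 (-3.22), Col12a1 (-2.62), Csrp1 (-1.97) and Btn1a1 (-1.32). Genes at or near 0 counts in a group had an adjusted p of 2.9e-05 for Igf1 and for Csn3, 3.7e-05 for Krt79, 6.8e-05 for Tll1, 7.8e-04 for Ovol1, 9.0e-04 for Tg, 0.0015 for Dio2 and 0.0037 for Acta2.

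The Wnt3a response differed for 308 genes. The lists differed with an adjusted p of 6.7e-06 for matrix genes, 3.1e-04 for G2 and mitosis genes, 0.0073 for the unfolded protein response, 0.0224 for chromatin regulators and 0.0326 for actin genes. With an estimated correlation 0 of these passed by camera. Log2 differences were 6.85 for Bcl11b, 2.50 for Nkd2, 1.34 for Znrf3, 1.27 for Fzd7, -3.48 for Col4a1, -4.02 for Axin2, -4.64 for Fbln2, -7.26 for Acta1 and -7.50 for Col2a1. An adjusted p alone is given for Igf1 (0.0013), Fgf13 and Runx3 (0.0029 each), Gramd1b (0.0049), Akr1c18 (0.0054), Adamts17 (0.0094) and Krt6b (0.0362).

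The G2 and mitosis genes fell further under TGFb in WT than in AE, with a median log2 difference of 2.88 over the 30 genes. Other library scalings left it at 2.56 or more, which argues against scaling as its cause. The treated levels also stood apart, with a median log2 ratio of AE over WT of 2.20 (quartiles 1.92 and 2.53, 30 of 30 genes above 0) against -0.63 in untreated cells, so a lower starting level in AE does not account for it. The A342E allele and another difference between the 2 lines cannot be told apart as its cause, since each genotype had 1 line. A weaker TGFb arrest in cells with the A342E allele stays open as an untested hypothesis.

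In the WT line replicate 1 differed from replicate 2 along the GC content of the transcripts, with a Spearman rho of -0.79 across genes, which are not independent replicates, and of 0.38 with transcript length. These values are consistent with a technical difference in library preparation or sequencing, and both trends held given the other (partial rho -0.775 and 0.312). A different share of dividing cells stays open, with a median log2 ratio of 0.18 over the S phase and G2 and mitosis genes (quartiles -0.18 and 0.49). No other biological explanation was tested, since replicates of a group share all labels. After the GC content and length correction the common coefficient of variation fell from 0.26 to 0.168, and the number of genes changed rose in every comparison.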

How the results depend on the processing

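The DESeq2, limma log2(CPM + 1), total-count, same-experiment, crossed-block, within-line block, Lars2 and GC content and length settings were chosen after the data were seen. Of the counts of genes changed, 81 stayed within 1.5 times of the reported one under another setting and 38 did not. Of the values of named genes, 2994 kept their direction and their side of the threshold, 139 no longer passed, 24 passed where they had not and 16 changed sign. No named gene that passed changed sign. With another library left out, 14 counts stayed within 1.5 times and 26 did not. Of the named genes' values 986 stayed, 135 no longer passed, 3 newly passed and 6 changed sign. Of the counts within gene lists 2332 stayed and 464 moved, against 711 and 249 with a library left out. Named genes that passed but lost it under at least 1 setting other than a single library left out were 2 of 34, 2 of 34, 1 of 25, 23 of 25, 7 of 30, 12 of 16 and 3 of 33, in the order used below. Of the gene list tests 61 passed at the preset correlation and 15 with the estimated one (in the order used below, 2, 5, 2, 0, 5, 0 and 1). The cause of a change was not tested unless it follows from the setting, such as fewer libraries.

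With the GC content and length correction the counts were 6004 (TGFb in WT), 3206 (TGFb in AE), 2595 (TGFb difference), 1904 (Wnt3a in WT), 2626 (Wnt3a in AE), 1060 (Wnt3a difference) and 9167 (AE against WT). With that correction and the libraries of 1 experiment alone they were 8795, 7111 and 6188 for TGFb, and 260, 1022 and 146 for Wnt3a. With the libraries of 1 experiment alone and no correction the counts were 7213, 4517 and 3890 for TGFb and 20, 357 and 8 for Wnt3a. With only the groups compared they were 5419 (TGFb in WT), 6944 (TGFb in AE), 3890 (TGFb difference), 3 (Wnt3a in WT), 536 (Wnt3a in AE) and 8 (Wnt3a difference). DESeq2 called 1291 genes for Wnt3a in WT and 703 for the Wnt3a difference. The latter was 731 with limma on log2(CPM + 1), 542 on log2(CPM + 0.1) and 708 after quantile scaling. A threshold of 1 on the log2 fold change left 4333 genes for AE against WT, and the 4-day untreated contrast 4583. Without the replicate 2 AE libraries of the 3-day set, Wnt3a changed 475 genes in AE and differed for 106.

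Leaving out 1 library gave 2101 to 2363 genes for TGFb in WT, 352 to 459 for TGFb in AE, 637 to 717 for the TGFb difference, 281 to 3139 for Wnt3a in WT, 577 to 1158 for Wnt3a in AE, 114 to 1897 for the Wnt3a difference and 5705 to 8317 for AE against WT. The lone library left in a group is assumed to vary like the other groups.

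Pygo2 passed in 1 case, as lower in AE with the GC content and length correction, and changed sign between settings. For the TGFb difference it was 0.012 with median-ratio scaling and DESeq2, 0.003 with quantile scaling, 0.283 with the GC content and length correction (0.294 with 1 experiment alone) and -0.111 to 0.079 without 1 library. For TGFb in WT it was -0.009 with total-count scaling and -0.204 (-0.217) with the correction, and for TGFb in AE -0.014 with total-count scaling and -0.004 to 0.186 without 1 library. With the correction it was -0.418 (-0.426) for Wnt3a in WT and 0.688 (0.693) for the Wnt3a difference. For Wnt3a in AE it was -0.035 without the replicate 2 AE libraries and -0.001 to 0.073 without 1 library. AE against WT gave 0.016 with total-count scaling and 0.13 with the 3-day contrast. Total-count scaling moved the median of all genes by 0.12 for Wnt3a in WT and by -0.12 for the Wnt3a difference.

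The labels do not pair the replicate numbers. Deviations of same-numbered libraries correlated at 0.56 and 0.20 for TGFb in WT and AE, at 0.72 and 0.39 for Wnt3a, and at -0.28 and -0.52 between the untreated lines at 4 and 3 days. With the replicate number as a block the counts were 3543, 1329, 1143, 552, 1223, 274 and 7018, in the order used above, none moved by over 1.5 times. Such a block cannot absorb deviations that run opposite in the lines. A block within each line gave 4866, 2181, 1784, 2250, 1894, 1188 and 8518 genes. With the numbers crossed between the lines the block gave 1620, 709 and 8192 genes for the TGFb difference, the Wnt3a difference and AE against WT.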

Other observations

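The test of a shift of AE cells toward the WT level under Wnt3a was chosen after the result was seen, and so was the set of genes changed by all treatments. TGFb and Wnt3a had their own untreated libraries, so the overlaps within a line share no control.

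In all 4 treatment comparisons 49 genes were higher and 22 lower. The higher ones included the cell cycle inhibitors Cdkn1a and Cdkn2b, Gadd45a, the matrix metalloproteases Mmp9, Mmp10, Mmp12 and Mmp13, and the hyaluronan synthase Has2. The lower ones included Id2, Prlr, Uhrf1, Steap4 and Ceacam1. With the 3-day libraries alone 7 of the 71 kept both Wnt3a calls, Cdkn2b alone of those named here, and Id2, Prlr, Uhrf1 and Cdkn1a lost a call without 1 library. In WT, 190 genes rose and 169 fell with both factors, where independent lists would share 43.7 and 34.4, together 4.6 times as many as independent lists give. In AE the shared genes were 303 and 199 against 36.8 and 27.0, a ratio of 7.87. A response shared by both factors is consistent with these values. Whether it comes from the pathways themselves or from a difference between treated and untreated culture was not tested.

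TGFb in WT and Wnt3a in AE changed genes along the difference between the lines. Across 13172 genes, which are not independent replicates, the TGFb change in WT correlated with the AE minus WT difference of the untreated 3-day libraries (Pearson r 0.36), with no library in common. The value was 0.39 over genes with a mean of at least 10 CPM over all libraries. Genes near 0 counts in WT but high in AE stay in that set, so low counts in WT are not excluded as its source. Given GC content and length the value was 0.34, which argues against these trends as its source. The Wnt3a change in AE had an r of -0.44 with the AE minus WT difference of the untreated 4-day libraries. This value is the pattern itself, so a shift toward the WT level stays open. Of the other pairs, TGFb in AE had an r of -0.12 and Wnt3a in WT of 0.04.

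The split of the 8 untreated libraries by line was ranked among all splits of these libraries. The real split gave 5932 of 12648 genes in a fit of these libraries alone, and 1 of the 35 splits into groups of equal size, the real one, gave as many. The highest other split gave 0 genes by the same edgeR test. The other splits mix the lines, so the line difference adds to their spread and favours a low count.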
